A study of Danio rerio with 132 samples.

How the data were processed

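Gene expression was measured in pools of whole zebrafish embryos (Danio rerio, Tübingen strain) held in 1 of 8 waters and collected at 8, 12, 16, 24, 36 or 48 hours post fertilisation. The waters were aquarium water, named Control in the labels, tap water (TAP), and 6 waters of an indirect potable reuse scheme, in which wastewater is treated in steps towards drinking water. The labels name these RAW, MF, AOP-1, RO, AOP-2 and FINAL. The treatment protocol lists them as FE, MF, AOP1, RO, AOP2 and FP, and RAW and FINAL were taken here as the first and last of that order, which the labels do not state. Per the labels' protocols, a dish held 50 embryos in 200 ml at 28 °C, an experiment had 96 dishes, and the pooled embryos were those that looked normal. The experiment was run as 3 independent exposures, so a replicate here is an exposure, and arrays with the same exposure number come from the same run. AOP-2 and FINAL have arrays in exposures 2 and 3 only. The 132 arrays fall into 48 groups of water and hour, with 3 arrays each, or 2 for AOP-2 and FINAL.

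Total RNA was amplified and labelled with Cy3 and hybridised for 17 h at 65 °C to Agilent arrays with 1 sample per array, per the labels' protocols. Per the file headers, Feature Extraction 11.0.1.1 made the deposited spot values, which are fluorescence intensity: the processed intensity has background subtracted and a spatial trend removed within the array, and is not scaled between arrays. The headers name the genome build Zv9. The authors also deposited a table of log2 values with 1 column per array. Limma is named in the submitters' processing notes. The background correction, the scaling and the filter behind that log2 table are not given in the sources used here, so what was done to the authors' values between scan and table stays unknown. Its column medians lay between 7.36 and 7.45, its values correlated with the log2 of the processed intensity of the same array at r of 0.985 to 0.997 across probes, and 6.46% of its cells were empty. That table served as an alternative to the processed intensity.

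The log2 of the processed intensity was computed from the deposited files for each array's 61657 spots that are not controls. Spots flagged as outliers were left out, and the other spots of the same probe were averaged. The 75th percentile of each array's probe values was then subtracted. Of 43603 probes, 36821 were kept because they lay well above background, by the scanner software's own test, on every array of at least 1 group. Levels are therefore on a log2 scale on which 0 is the array's 75th percentile. Probes were named through the RefSeq accession in the array files and a RefSeq table of assembly GRCz12tu, used for names only; 25639 of 27186 probes with a curated mRNA accession matched. Kept probes with a symbol numbered 23746 and covered 12333 genes. No coordinates are given, because the reference is of another build than the arrays. The 75th percentile of the processed intensity ran from 370 to 1578 over the arrays, with a median of 812, and the share of spots well above background from 52.4% to 93.3%, with a median of 73.3%. The number of arrays limits the precision of every value.

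Differences were tested with limma 3.58.1 in R 4.3.3 (tables read with version 1.17.8 of data.table), with empirical Bayes moderation and an intensity trend, in a model with a mean for each of the 48 groups, 84 residual degrees of freedom and no other term. Benjamini-Hochberg adjustment at 0.05 was made over probes within each comparison. Each comparison of 2 waters is the mean over the 6 hours of their difference, so 18 arrays stand against 18. AOP-2 and FINAL were compared within a fit of the 96 arrays of exposures 2 and 3 (48 residual degrees of freedom), 12 arrays against 12. Differences at single hours, a moderated F test that a difference is equal at all hours, and steps of the Control time course came from the same fits. Tests were on both sides throughout. Errors are standard errors of the fit (SE) or 95% intervals, and "pairs" are arrays of a water and of Control from the same exposure and hour. The fit counts the 6 hours of an exposure as independent. With 3 exposures, or 2 for AOP-2 and FINAL, its intervals and p do not measure the spread of a difference between exposures.

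The exposures are separate runs of the experiment, so the exposure number pairs the arrays. Over arrays of the same hour and different waters, deviations from group means correlated with a median r of 0.19 between arrays of the same exposure (426 pairs, 269 of them above 0.1) and of -0.09 between different exposures (840 pairs, 189 above 0.1). Deviations cancel within a group, so a positive value for the same exposure brings a negative one for different exposures. The second value is thus no separate evidence of pairing. A fit with the exposure within each hour as a block was planned as the alternative. That fit removes what the waters of an exposure share at an hour, not a difference between waters that varies by exposure. Its counts stand beside those of the averaged comparisons and, at single hours, beside the counts that it moved most. The arrays lie on 18 slides of 4 to 8 arrays, scanned on 5 days with each slide scanned on 1 day, and slides hold several waters, hours and exposures. Differences within a scan day or a slide take arrays of the same hour, which can be of different exposures.

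Gene lists, 36 in number and covering responses to chemicals, stress, tissues and stages, were tested with camera at a preset correlation of 0.01 between genes, with 1 probe per gene, and again with an estimated correlation. The adjustment ran over all 252 tests of a list and a water, and over the lists and steps of the time course. The hour each array resembled was estimated by correlation with the mean profiles of the other exposures, on a grid of 0.25 h, and compared between waters by sign-flip permutation over pairs. Shares of variance came from sequential sums of squares, with 100 permutations of the water names within exposure and hour.

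The genes named were chosen by a rule. For each comparison these are, among genes past the threshold with a symbol, the same sign in every exposure and a signal well above background on all arrays of both waters at 1 or more hours, the 12 largest rises and 12 largest falls. The probe with the highest mean among a gene's passing probes was taken, so a brighter probe that did not pass was left out. Where fewer than 5 genes passed, the 5 with the smallest p are given. At single hours and at each step of the time course the 3 largest rises and falls are given, and list members may be named with their list. The design, the tests, the lists and this rule were fixed before the data were examined. The alternatives were normexp background correction of the median spot and local background intensity with an offset of 50 (the mean spot intensity that had been planned is not in the files), quantile or median scaling, the authors' log2 table, other filters on dim probes, blocks for exposure, slide or label date, other variance models, fits of the 2 waters alone, other list tests, and leaving out each exposure.

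The fits were tested on simulated data with 67, 67 and 66 probes changed by a log2 of 0.5, 1 and 2 among 36821. Errors were drawn independently for each array, with no exposure effect and no stray values, so the shares below hold for such errors only. For RAW against Control as a mean over hours, 56.7%, 82.1% and 98.5% of these were called, with 7 false calls. At 12 h alone the shares were 2.99%, 29.9% and 63.6%. For AOP-2 against Control as a mean over hours they were 46.3%, 80.6% and 98.5%. A planted shift of 1 h in the RO arrays before 48 h was read as 1.13 h over those hours. Arrays of 48 h could not be moved later, so the mean over all hours was not tested this way.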

Results

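Expression profiles of whole zebrafish embryos were collected from 132 one-colour arrays, 18 each for Control, TAP, RAW, MF, AOP-1 and RO and 12 each for AOP-2 and FINAL, spread evenly over 6 hours of development. The hours were sampled to catch effects of the waters that come and go during embryogenesis, per the labels' protocols. Arrays of the same water and hour from different exposures correlated with r between 0.917 and 0.989 across probes (120 pairs, median 0.978), and the SD of their log2 differences lay between 0.48 and 1.50. The array with the lowest share of spots well above background was the RAW 12 h array of exposure 1, at 52.4%. All counts below are of probes out of 36821 tested with limma unless genes are named.

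Development in aquarium water gave the largest differences in the data. Between 8 h and 48 h, genes of contracting muscle rose most: actc1b, a muscle actin, from -3.20 ± 1.19 to 8.62 ± 0.27 (log2 level ± SD, n = 3 and 3), followed by pvalb1, a calcium-binding parvalbumin, by a log2 of 11.70 (SE 0.52), the myosin light chain mylz3 by 10.80, the adenylate kinase ak1 by 10.25, the troponin tnnt3b by 10.21, the creatine kinase ckma by 10.16 and the actinin actn3a by 9.31. The retinol carrier rbp4 rose by 10.00, the lens crystallin cryba1l1 by 9.66, the embryonic globin hbae3 by 9.57, the collagen col1a2 by 9.41 and the brain fatty acid-binding gene fabp7a by 9.24. Genes of the early embryo fell most: the cathepsin ctsll (log2 -11.06, SE 0.47), the hydrolase urahb (-10.09), the caudal homeobox gene cdx4 (-9.53), the egg-coat genes zp3.1, zp2.6 and zp3 (-8.51, -8.40 and -8.32), the T-box gene tbx16l (-8.51), pnhd (-8.40), the ventral homeobox gene vox (-8.31), the pluripotency factor pou5f3 (-8.18), the keratin krt99 (-7.86) and cdx1a (-7.59). All 24 had a limma adjusted p of 7.05e-16 or less. In all, 24339 probes (66.1%) passed, 10867 higher and 13472 lower at 48 h. The median of all probes stood at -0.22, and at -0.50 with median scaling, so changes near these sizes depend on the scaling. With normexp background correction the split was 8647 higher and 16989 lower.

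The steps of the time course differed in size and in the genes that led them. From 8 to 12 h, 5501 probes rose and 4938 fell, led by actc1b, rbp4 and the peroxisomal oxidase hao1 (log2 6.91, 6.16 and 5.92) against the endoderm gene sox32 (-6.74), the nodal antagonist lft2 (-6.03) and si:dkeyp-114g9.1 (-4.94). From 12 to 16 h, 2863 rose and 2172 fell, with the calcium pump atp2a1 (7.99), the myosin light chain mylpfa (7.02) and the embryonic globin hbbe3 (6.79) ahead, and pnhd (-4.15), the lipoxygenase alox5b.3 (-3.96) and cart4 (-3.95) at the other end. From 16 to 24 h, 3858 rose and 4333 fell. The lens crystallins crygm2d3 (11.10) and crygm2d10 (10.92) and the troponin tnnt3b (9.28) rose most in that step, and the presomitic mesoderm genes msgn1 (-6.01) and tbx6 (-5.73) and the urate oxidase uox (-4.53) fell most. From 24 to 36 h, 1371 rose and 1649 fell, with the photoreceptor factor crx (5.71), zgc:136930 (4.45) and crabp1a (4.45) against cyp4t8 (-3.70), urahb (-3.19) and tnni2b.1 (-2.76). From 36 to 48 h, 764 rose and 792 fell: the retinal gene rs1a (5.70), the collagen col10a1a (5.61) and the cone transducin gene gnb3a (5.56) rose, and hbbe3 (-2.94), the cathepsin ctss2.1 (-2.91) and si:ch1073-464p5.2 (-2.80) fell. The largest limma adjusted p among these was 0.00132, with SE between 0.29 and 1.27. Median scaling gave 2776 higher and 1058 lower for 12 to 16 h and 552 and 318 for 36 to 48 h. Normexp gave 3929 and 5649 for 8 to 12 h, 1952 and 1514 for 24 to 36 h and 1301 and 819 for 36 to 48 h.

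Tissue and stage lists moved with the course. Between 8 and 48 h all 23 tested genes of the skeletal muscle list rose (camera adjusted p = 2.13e-18, and adjusted p = 0.0373 with an estimated correlation). Of the eye and lens list 18 of 22 rose, and of the neuron list 18 of 19. Their camera adjusted p were 2.16e-08 and 4.53e-10, and adjusted p = 0.162 and adjusted p = 0.113 with an estimated correlation. Of the gastrula and mesendoderm list 21 of 22 fell, of the maternal and germ line list 15 of 16, of the proliferation list 18 of 19 and of the somitogenesis list 14 of 17 (camera adjusted p = 4.23e-09, 0.000328, 5.09e-07 and 4.89e-06). With an estimated correlation these were adjusted p = 0.0771, 0.406, 0.162 and 0.113. The counts adjusted over the list alone were 23, 18, 18, 22, 16, 18 and 15 genes in that order, from skeletal muscle to somitogenesis. Over single steps, the calls that held with an estimated correlation included gastrula genes falling from 8 to 12 h (18 of 22 fell, adjusted p = 0.0373), erythroid genes rising from 12 to 16 h (8 of 12, 0.00807), and pigment cell genes rising from 16 to 24 h (9 of 12, 0.000848) while somitogenesis genes fell (14 of 17, 0.00238). From 24 to 36 h glucocorticoid-responsive genes rose (5 of 14, 0.000438) and proliferation genes fell (12 of 19, 0.0178). From 36 to 48 h circadian clock genes rose (7 of 23, 0.0271) and proliferation genes fell (10 of 19, 0.00377).

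Hour of development took 77.3% of the variance over kept probes, the exposure within an hour 6.86%, the water 0.873% and the water by hour 4.23%. In 83 of 100 permutations of the water names within exposure and hour the share of water was as large or larger (median 0.987%), and in 97 of 100 the share of water by hour was (median 4.95%). Over all probes together, the shares of water were therefore within what chance gives.

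The hour that each array resembled was compared between waters because a faster or slower embryo differs in many genes. RO arrays resembled an hour 0.556 h later than their Control partners (SD 0.953, higher in 10 and lower in 3 of 18 pairs, permutation p = 0.0199, adjusted over 7 waters 0.139). MF arrays differed by 0.556 h (SD 1.06, permutation p = 0.0444, adjusted 0.156) and RAW arrays by 0.75 h (SD 3.15, permutation p = 0.395), which was 0.118 h without the RAW 24 h array of exposure 1 and -0.312 h without exposure 1. In exposure 3 the RAW array resembled an earlier hour than the Control array at 5 of 6 hours (at 16 h, 14.5 against 15.75 h). No water passed after adjustment, by the permutation test, and 2 of 7 had an unadjusted p under 0.05. Some arrays stood apart: the RAW 24 h array of exposure 1 resembled 33.75 h, the AOP-1 36 h array of exposure 3 resembled 42.75 h and the RAW 36 h array of exposure 2 resembled 42 h. At 48 h the arrays of exposure 1 resembled 41.25 to 43.5 h and those of exposures 2 and 3 44.75 to 48 h.

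**Figure D1:**
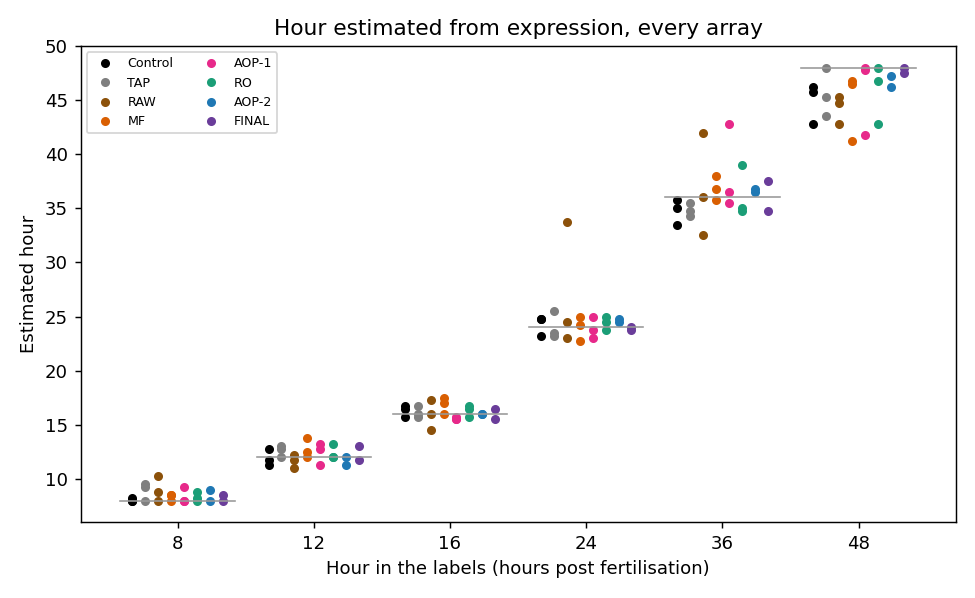
Estimated hour of each of the 132 arrays (vertical axis, hours post fertilisation) against the hour in its label (horizontal axis); each point is an array, coloured by water, and the grey lines mark the labelled hours. The RAW 24 h array of exposure 1 stands apart at 33.75 h.

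Embryos in RAW, taken here as the first water of the treatment series, were compared with Control to ask what this water does to expression. The dioxin-responsive cytochrome cyp1a (NM_131879), which the aryl hydrocarbon receptor (AhR) induces, was 8.53-fold higher in RAW (95% interval 4.73 to 15.4, limma adjusted p = 2.8e-06) and higher in 18 of 18 pairs. From 12 h on its level in RAW lay between 3.00 ± 0.13 (SD, n = 3, 16 h) and 4.15 ± 0.11 (48 h), against -0.30 ± 0.45 (12 h) to 1.02 ± 0.57 (36 h) in Control. At 8 h it was well above background on 1 of 3 Control arrays and ranged widely in RAW (0.11 ± 3.90). The second AhR target cyp1b1 was 3.90-fold higher (2.39 to 6.37, adjusted p = 0.00211, 17 of 18 pairs), most at 12 h, where its log2 difference was 5.27 (SE 0.87) with 1 of 3 Control arrays above background. The oxygen sensor egln3, a prolyl hydroxylase, was 2.49-fold higher (1.89 to 3.28, adjusted p = 4.16e-05, 14 of 18 pairs), and the cytochrome oxidase subunit cox6b1 2.04-fold (1.53 to 2.73, 0.0206, 16 of 18). The mesendoderm homeobox gene mixl1 was higher too (adjusted p = 0.00211, 13 of 18 pairs), but was well above background on 12 of 18 RAW and 7 of 18 Control arrays, so no fold over all hours is given. These are the 5 genes with a symbol among the 10 probes that rose. No probe fell by limma. At an unadjusted p of 0.05, 872 passed in either direction, and 1978 with the exposure block, where evenly spread p would give 1841. The count moved with the fit, so setting it against 1841 does not measure how much signal there is. With the exposure block 27 probes rose and 0 fell, and the AhR repressor ahrra (log2 0.80), the glycolytic genes ldha (0.34) and eno1a (0.51), the collagen hydroxylases p4ha1b (0.46) and plod1a (0.32) and the stress factor atf3 (0.52) were among them.

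The RAW calls rest in part on exposure 3. Without it, 0 probes passed (limma; 817 at an unadjusted p under 0.05), cyp1a at a log2 of 2.73 with adjusted p = 1. With the exposure block and without exposure 3, 8 probes passed and cyp1a had adjusted p = 1.78e-05, cyp1b1 0.0122 and egln3 0.181. Without exposure 2 the count was 6 and cyp1b1 missed the threshold at a log2 of 1.82 (adjusted p = 0.201). Without the RAW 12 h array of exposure 1 the count was 10, and without the RAW 24 h array of exposure 1 it was 8. The other probes of mixl1 had a log2 of 0.81 each (adjusted p = 1), and its call ended with quantile scaling, with the authors' table and without any 1 of the exposures. Within the 3 scan days that held both waters at the same hour, the cyp1a difference was 2.18 to 3.52, and cox6b1 ran from -0.19 to 1.24. Both low ends came from a day that held both waters only at 24 h. There the RAW array of exposure 1 that resembled 33.75 h stood against a Control array of exposure 3. Exposure and stage are therefore mixed into those low ends. On the 4 slides that held both waters at the same hour egln3 ran from -0.70 to 3.51, with the sign of its mean on 2. Those pairs of arrays were of exposures 1 and 2 only, so they do not cover exposure 3, on which the egln3 call depends.

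Among the usual readouts of exposure, only cyp1a passed in RAW. The metallothionein mt2 (log2 0.10, SE 0.12), the heat shock gene hsp70l (0.39, SE 0.19), the retinoid hydroxylase cyp26a1 (-0.21, SE 0.11), the calcium channel trpv6 (-0.21, SE 0.25) and the stanniocalcin gene stc1l (-0.57, SE 0.35) each had a limma adjusted p of 1. The oestrogen readouts vtg1 and cyp19a1b did not pass the background filter and were not tested. As lists, the AhR-responsive genes were higher in RAW (camera adjusted p = 2.66e-07, and adjusted p = 0.00817 with an estimated correlation; 2 of 12 tested genes passed over all genes and 3 adjusted over the list alone, with ahrra the third; with the block 5 did, cyp1c1 and foxq1b among them). The hypoxia list was higher (3.29e-11, and adjusted p = 0.000294 with an estimated correlation). Of its 18 genes 1 passed over all genes and 5 adjusted over the list alone: egln3, p4ha1b, the aldolase aldocb (0.36), ldha and the glycolytic regulator pfkfb3 (0.30). The maternal and germ line list was higher (5.19e-12, and adjusted p = 0.0314 with an estimated correlation), with 0 of 16 genes past limma's threshold over all genes and 5 adjusted over the list alone: btg4 (1.3), h1m (1.03), cldnd (0.82), tdrd7a (0.74) and cldng (0.55), genes whose transcripts the egg supplies. As most RAW arrays of exposure 3 resembled an earlier hour than Control, this rise is not separated from stage. The gastrula and mesendoderm list lost its call (9.24e-07, and adjusted p = 0.279 with an estimated correlation); sox32 (1.44), mixl1 and vox (0.31) passed adjusted over the list alone.

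MF and AOP-1, the next waters in the series, raised the same AhR targets against Control. In MF, cyp1a was 8.16-fold higher (95% interval 4.53 to 14.7, limma adjusted p = 5.59e-06, 18 of 18 pairs) and cyp1b1 3.39-fold (2.07 to 5.53, adjusted p = 0.0294, 17 of 18). In AOP-1, cyp1a was 6.15-fold higher (3.41 to 11.1, adjusted p = 0.000423, 17 of 18 pairs) and cyp1b1 3.95-fold (2.42 to 6.45, adjusted p = 0.00342, 15 of 18). By 48 h cyp1a had reached 4.46 ± 0.40 in MF and 4.50 ± 0.82 in AOP-1, against 0.72 ± 0.65 in Control (SD, n = 3). These were the only genes with a symbol among the 5 probes that rose in MF and the 4 in AOP-1; 0 fell in either (limma; 483 and 399 at an unadjusted p under 0.05). In the fit with the block 8 probes rose in MF, ahrra among them (log2 0.90, blocked adjusted p = 0.00387). The AhR-responsive list was higher in MF (camera adjusted p = 2.86e-14, and adjusted p = 3.9e-05 with an estimated correlation) and AOP-1 (2.66e-07, and adjusted p = 0.00817). In each, 2 of 12 genes passed over all genes and 3 adjusted over the list alone. Next by p but not past the threshold were cep290 (-0.21) and nkx3.3 in MF and the arginase arg1 (0.74), isoc2 (0.26) and hif1al (0.18) in AOP-1. No difference is given for nkx3.3, which was above background on 0 of 3 MF arrays at 8, 12 and 16 h.

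Counts of calls in MF and AOP-1 moved with the arrays used. Without exposure 3, 0 probes passed in MF and 0 in AOP-1, with cyp1a at a log2 of 2.47 and 2.38 (limma; 356 and 333 at an unadjusted p under 0.05); with the exposure block and without exposure 3, 3 and 4 passed, and cyp1a had adjusted p = 0.000185 in MF and 0.000419 in AOP-1, while cyp1b1 missed the threshold (0.283 and 0.188). It also missed it without exposure 2 (adjusted p = 0.216 in MF and 0.31 in AOP-1), and passed there with the block (0.0181 and 0.0343). Without exposure 2 the AOP-1 count was 1 and cyp1a in AOP-1 had a log2 of 2.26 (adjusted p = 0.0926, and 0.000425 with the block). Fitted on the arrays of the 2 waters alone, AOP-1 gave 0 (limma; 270). The exposure block gave 5 in AOP-1. With slide as a block cyp1b1 in MF missed the threshold (adjusted p = 0.111) at a log2 of 1.78, against 1.76 without. On both slides that held AOP-1 and Control at the same hour, cyp1b1 lay below Control in AOP-1 (-0.20 and -0.13). These were exposure 1 arrays of 24 and 36 h. At those hours the AOP-1 difference over all exposures was small (0.38 and 0.40, against 4.96 at 12 h). The slides therefore say little about slide as a cause. Within scan days cyp1a differed by 1.89 to 4.40 in MF and by 1.95 to 3.55 in AOP-1.

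**Figure D2:**
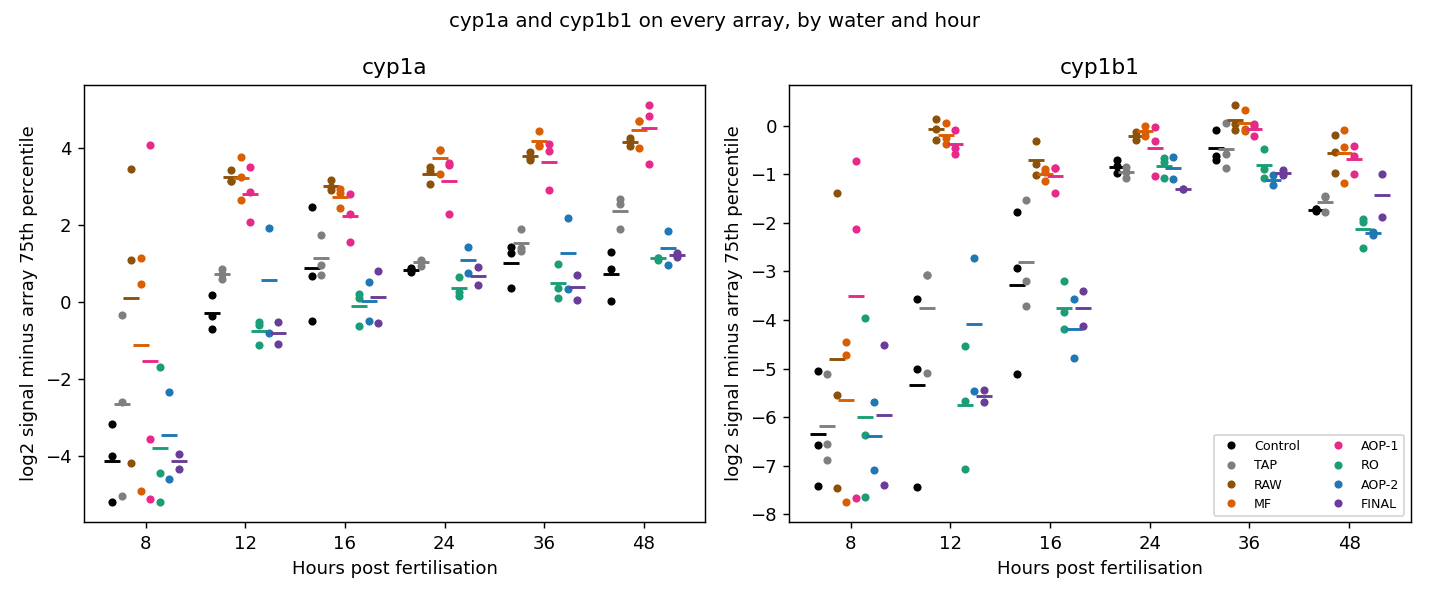
Levels of cyp1a and cyp1b1 (vertical axis, log2 signal minus the array's 75th percentile) by hour post fertilisation (horizontal axis); each point is an array, coloured by water, and dashes are group means. At 48 h cyp1a averaged 4.15 in RAW, 4.46 in MF and 4.50 in AOP-1, and 0.72 in Control.

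RO embryos showed another set of genes against Control. The genes irg1l, a relative of an immune-responsive decarboxylase, and tcnbb, a cobalamin-binding transcobalamin, were 2.86-fold (95% interval 2.08 to 3.93, limma adjusted p = 4.64e-05, 16 of 18 pairs) and 2.61-fold higher (1.88 to 3.63, 0.000452, 13 of 18). The glutathione transferase gstp1.2 was 1.56-fold higher (1.35 to 1.80, 0.000165, 17 of 18), the sulfide oxidising enzyme sqor 1.45-fold (1.28 to 1.65, 0.000457, 16 of 18) and si:ch211-93g23.2 1.93-fold (1.49 to 2.52, 0.00855, 15 of 18). The annexins anxa1c and anxa1d fell to 0.738 (0.668 to 0.815, 0.000165) and 0.755 (0.674 to 0.847, 0.0116) of Control, and were higher in 2 and 3 of 18 pairs. In all 17 probes rose and 3 fell, with 9 genes; the methyltransferases tpmt.1 and tpmt.2 passed but did not have the same sign in every exposure. The largest change was on a pair of probes with no symbol, both for XM_001344137, with log2 differences of 3.27 and 3.14, chosen here after their values were seen. The AhR target cyp1a was at a log2 difference of -0.29 (SE 0.43). With the exposure block 29 probes rose and 11 fell, and the retinoid hydroxylase cyp26a1 then passed (log2 -0.42, blocked adjusted p = 0.00838).

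Lists in RO moved for oxidative stress and for skin. The oxidative stress (Nrf2) list was higher (camera adjusted p = 1.13e-08, and adjusted p = 0.0205 with an estimated correlation), with 1 of 19 genes past over all genes and 4 adjusted over the list alone: gstp1.2, the peroxiredoxin prdx1 (log2 0.37), the glutathione reductase gsr (0.29) and keap1a (0.25). The epidermis and keratin list was lower (1.4e-11, and adjusted p = 0.0263 with an estimated correlation), with 1 of 22 past over all genes and 1, anxa1c, adjusted over the list alone; with the exposure block 9 passed adjusted over the list alone, among them krt5 (-0.21) and ppl (-0.21). The skeletal muscle list was higher at the preset correlation (2.96e-06, and adjusted p = 0.718 with an estimated correlation), as was the circadian clock list (0.000614, and adjusted p = 0.279; 0 of 23 genes by limma adjusted over the list alone, 6 with the block).

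The RO calls also depended on the exposures, since the exposure 1 differences were the smallest for each of these 7 genes (gstp1.2 0.25 in exposure 1, 0.88 in exposure 2 and 0.79 in exposure 3). Without exposure 3, 0 probes passed (limma; 486 at an unadjusted p under 0.05), without exposure 2, 1 passed and without exposure 1, 42. With the block and without exposure 3, 9 passed, gstp1.2 among them (adjusted p = 0.00644) but not sqor (0.258); with the block and without exposure 2 neither passed (adjusted p = 0.126 and 0.999). With median scaling the 3 falls missed the threshold, anxa1c at a log2 of -0.45 (adjusted p = 0.179) and anxa1d at -0.42. The rise of tcnbb, above background on 9 of 18 Control arrays, shrank to a log2 of 0.56 with normexp and 0.43 in the authors' table, from 1.38, and that of si:ch211-93g23.2, above background on 10 of 18, to 0.25 and 0.57, from 0.95, and neither passed there. Of 4 scan days with both waters, 1 day went the other way for irg1l (-0.17), tcnbb (-0.93), si:ch211-93g23.2 (-0.21) and gstp1.2 (-0.59). That day held both waters only at 8 h, with the RO array of exposure 1 against the Control array of exposure 3. It therefore does not separate scan day from exposure. Scan days 1 and 3 held a single hour each as well. With slide as a block irg1l stood at 1.43 (adjusted p = 0.000265) and gstp1.2 at 0.62 (0.000751), and tcnbb, sqor, anxa1c and anxa1d also passed. The calls of si:ch211-93g23.2 (log2 0.83, adjusted p = 0.0934), tpmt.1 (adjusted p = 0.229) and tpmt.2 (0.188) ended there.

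**Figure D3:**
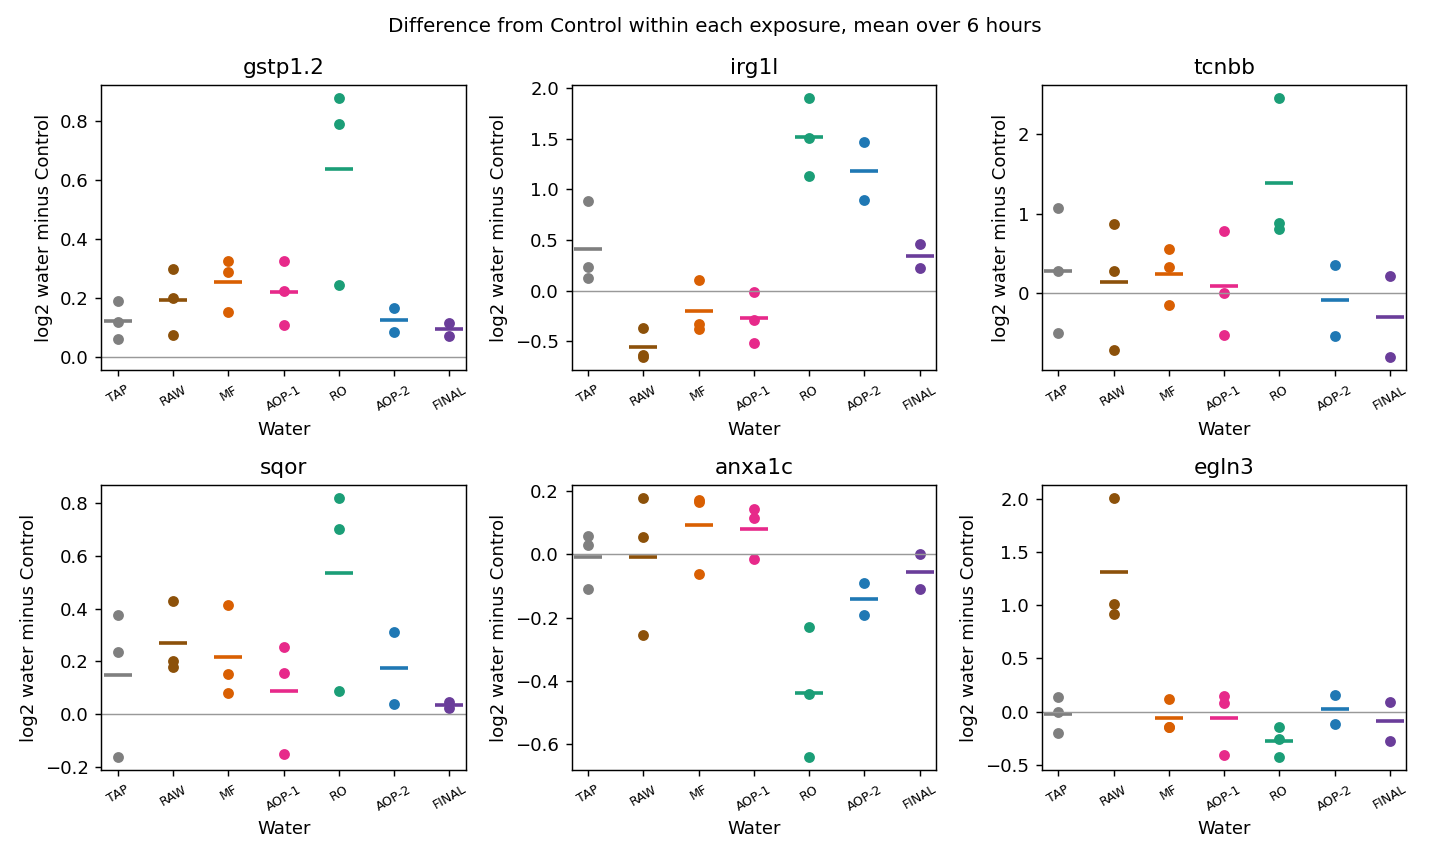
Difference from Control (vertical axis, log2) for gstp1.2, irg1l, tcnbb, sqor, anxa1c and egln3 in each water (horizontal axis); each point is the mean over 6 hours within an exposure and the dash is their mean. In RO, gstp1.2 lay at 0.25, 0.88 and 0.79 in exposures 1, 2 and 3.

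Tap water was compared with Control as the other water people drink and handle. No probe passed in TAP by limma, with or without the exposure block. At an unadjusted p under 0.05 there were 391, and 1152 with the block, where evenly spread p would give 1841. The genes with the smallest p were csnk2a1, a casein kinase subunit (log2 -0.53, SE 0.13, lower in 16 of 18 pairs), ch25hl1.1 (0.32, SE 0.09), csf1a (-0.34), the protease gene prss59.1 and the ammonium transporter gene rhcga, each with a limma adjusted p of 1. The probes of the last 2 lie near background, above it on 0 and 2 of 18 TAP arrays and 2 and 4 of 18 Control arrays, so no difference is given for them. The cyp1a difference was 0.85 (SE 0.43, adjusted p = 1), higher in 16 of 18 pairs; adjusted over the AhR-responsive list alone its p was 0.61, and 0.0403 with the block. Genes for ribosomal proteins lay above 0 in 79 of 80 cases with a median of 0.13 (camera adjusted p = 2.54e-43, and adjusted p = 0.279 with an estimated correlation); 0 passed by limma over all genes or adjusted over the list alone, and with the exposure block 13 passed adjusted over the list alone.

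AOP-2 and FINAL, taken here as the last waters, were compared with the Control arrays of exposures 2 and 3. In AOP-2 the cholesterol 25-hydroxylase-like gene ch25hl1.1 was 1.50-fold higher (95% interval 1.31 to 1.71, limma adjusted p = 0.00598, 8 of 12 pairs) and the annexin anxa1b 1.39-fold (1.23 to 1.57, adjusted p = 0.0267, 9 of 12). In FINAL they were 1.52-fold (1.33 to 1.73, adjusted p = 0.00283, 9 of 12) and 1.39-fold higher (1.23 to 1.57, adjusted p = 0.0349, 11 of 12). No other probe passed in either water and 0 fell (limma; 363 and 686 at an unadjusted p under 0.05). By hour, the log2 of ch25hl1.1 was 1.52 at 36 h and 1.49 at 48 h in AOP-2, and 1.57 and 1.48 in FINAL (SE 0.24), and between -0.09 and 0.33 at the 4 earlier hours in AOP-2. For anxa1b it was 1.62 in AOP-2 and 1.49 in FINAL at 48 h and at most 0.46 at the other hours. The test that a difference changes between hours did not pass for either gene in either water (limma adjusted p = 0.0567 and 0.0799 for ch25hl1.1, 0.267 and 1 for anxa1b), and with the exposure block it passed for ch25hl1.1 (adjusted p = 0.0292 and 0.0411), so a late start is not established for both. The cyp1a difference was 0.27 in AOP-2 and -0.29 in FINAL (SE 0.42). Not past the threshold but next by p were zgc:100868 (0.60), irg1l (1.18) and the prostacyclin synthase ptgis (0.35) in AOP-2, and ptgis (0.41), zgc:100868 (0.48) and tbca (0.32) in FINAL. With median scaling 0 probes passed in either (limma; 361 and 534 at an unadjusted p under 0.05). With 1 exposure left out some calls missed the threshold with the difference still present: ch25hl1.1 without exposure 2 (log2 0.47 and 0.52, adjusted p = 0.823 and 0.669), and anxa1b without exposure 3 (0.49 and 0.53, adjusted p = 0.238 and 0.0665) and without exposure 2 (0.46 and 0.41, adjusted p = 0.582 and 1). The exposure block gave 2 calls in AOP-2 and 3 in FINAL. The counts were 5 and 3 without exposure 2 and 12 and 38 without exposure 3. With slide as a block ch25hl1.1 missed the threshold in both (0.0592 and 0.135) at a log2 of 0.53 and 0.55, against 0.58 and 0.60 without. In that fit anxa1b passed in AOP-2 (log2 0.50, adjusted p = 0.0243) and not in FINAL (0.45, 0.152). The anxa1b calls also ended in both waters with normexp, with quantile scaling, in the authors' table and with moderation without a trend. They ended as well with Control of all 3 exposures and in the fit of the 2 waters alone. Within the 2 scan days with both waters ch25hl1.1 differed by 0.54 and 0.64 in AOP-2, and by 0.44 and 0.57 in FINAL.

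**Figure D4:**
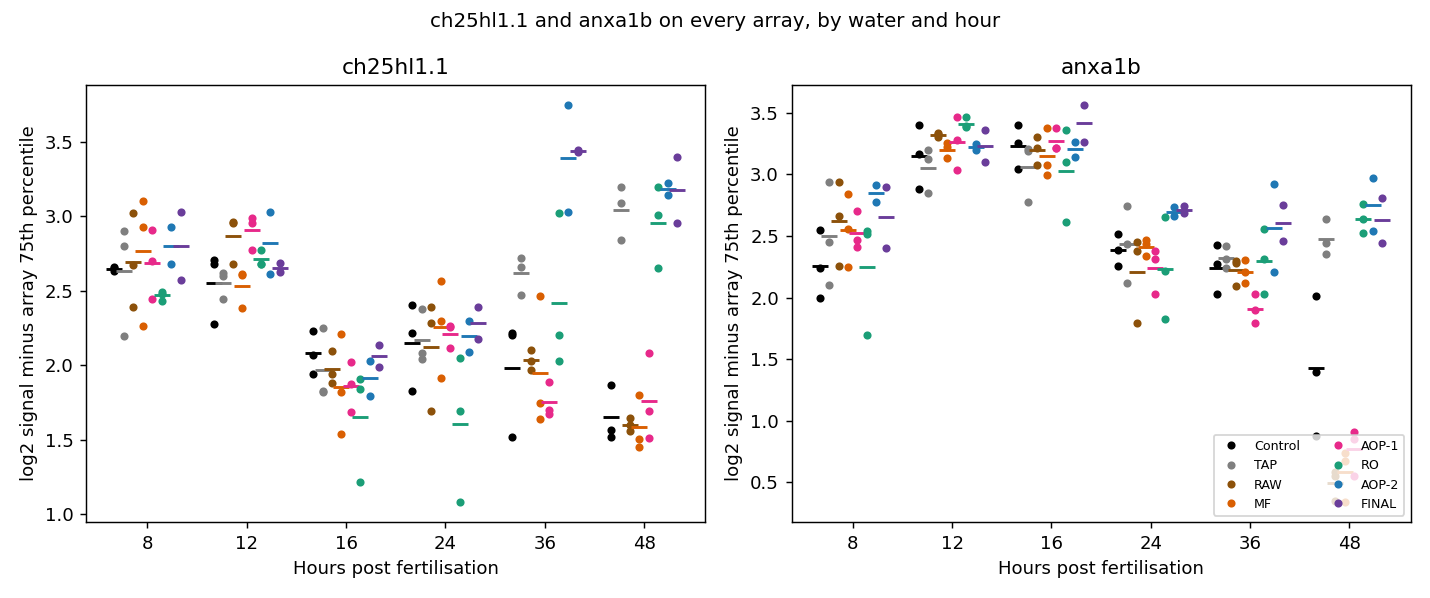
Levels of ch25hl1.1 and anxa1b (vertical axis, log2 signal minus the array's 75th percentile) by hour post fertilisation (horizontal axis); each point is an array, coloured by water, and dashes are group means. At 48 h ch25hl1.1 lay 1.39 above Control in TAP, 1.3 in RO, 1.49 in AOP-2 and 1.48 in FINAL, and within 0.11 of it in RAW, MF and AOP-1.

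Each step of the treatment series was then compared with the water before it. From RAW to MF, egln3 fell to 0.387 of its RAW level (95% interval 0.294 to 0.51, limma adjusted p = 3.47e-05, lower in 17 of 18 pairs) and mixl1 was lower (adjusted p = 0.0235, lower in 13 of 18; above background on 10 of 18 MF and 12 of 18 RAW arrays). They were the genes of the 3 probes that fell, and 0 rose (1194 at an unadjusted p under 0.05). The fit with the block had 6 that fell, among them the lactate dehydrogenase ldha (log2 -0.37) and the homeobox gene nkx3.3. The latter was above background on 0 of 3 MF arrays at 8, 12 and 16 h, so no difference over all hours is given. The dehydrogenase gene idh1 was higher in 15 of 18 pairs (0.23) without passing (limma adjusted p = 0.841). The cyp1a difference between MF and RAW was -0.06 (SE 0.43). Without exposure 3 no probe passed (0 by limma, 637 at an unadjusted p under 0.05), egln3 at -0.98, and the mixl1 call also ended without any 1 of the exposures, with or without the block, with quantile scaling, in the authors' table and with slide as a block (-1.26, adjusted p = 0.076). With the block and without exposure 3 it was 0 as well (1918). From MF to AOP-1 no probe passed (0 by limma, 381 at an unadjusted p under 0.05, 0 with the block); the smallest p belonged to gjb1a (0.84), srd5a2a (0.91), l3mbtl2 (0.20), xpo7 (0.61) and pks1 (0.48).

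From AOP-1 to RO the AhR targets fell back. The level of cyp1a in RO was 0.133 of that in AOP-1 (95% interval 0.074 to 0.24, limma adjusted p = 6.85e-06, lower in 18 of 18 pairs) and that of cyp1b1 0.219 (0.134 to 0.358, 0.000116, lower in 16 of 18). The annexins anxa1c and anxa1d fell to 0.698 (0.632 to 0.771, 1.82e-06) and 0.767 (0.685 to 0.86, 0.0268). At the same step irg1l rose 3.45-fold (2.51 to 4.75, 1.99e-07), tcnbb 2.47-fold (1.77 to 3.43, 0.00172), sqor 1.37-fold (1.2 to 1.55, 0.0131) and zgc:100868 1.33-fold (1.18 to 1.51, 0.0321). These were the 8 genes of 12 probes that rose and 8 that fell; with the exposure block 24 rose and 20 fell. Without exposure 3, 1 probe passed, that of irg1l (adjusted p = 0.0138), and with the block and without exposure 3, 7 passed, cyp1a among them (adjusted p = 1.51e-05). Without exposure 2, 6 passed and without exposure 1, 38. Within the 4 scan days cyp1a differed by -3.68 to -2.20, and tcnbb by -1.10 to 2.02. Over the alternatives the tcnbb rise ran from a log2 of 0.44 to 1.55 and passed in 12 of 18. It missed the threshold with normexp, in the fit of the 2 waters alone, and without exposure 2 or 3.

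From RO to AOP-2, measured in exposures 2 and 3, 26 probes passed. The glutathione transferase gstp1.2 fell to 0.612 of its RO level (95% interval 0.556 to 0.673, limma adjusted p = 6.39e-10, lower in 12 of 12 pairs) and tcnbb to 0.293 (0.212 to 0.406, 2.54e-06). Falls were also called for the glucuronosyltransferase ugt1a1, to 0.558 (0.0161), tpmt.2 to 0.64 (7.84e-06), tpmt.1 to 0.696 (0.00066), prdx1 to 0.665 (0.00066), sqor to 0.665 (0.000158) and gsr to 0.743 (0.000239), as did si:ch211-93g23.2 to 0.54 (0.0212). The genes that rose were ch25hl1.1 1.46-fold (1.28 to 1.67, 0.00118), the glycosyltransferase b3gnt3.1 1.40-fold, the calpain capn9 1.40-fold, anxa1c 1.32-fold, ckap4 1.28-fold and the keratin cyt1l 1.26-fold, with adjusted p from 0.00118 to 0.0374. In all 7 probes rose and 19 fell, with 15 genes. The exposure block gave 15 and 20, with quantile scaling 14 and 18, with normexp 13 and 18, and with median scaling 1 and 7. Over the alternatives the fall of tcnbb ran from a log2 of -2.11 to -0.77, and within scan days from -2.80 to 0.12. That of si:ch211-93g23.2 ran from -0.96 to -0.24 over the alternatives. Its call ended with normexp, with quantile or median scaling, in the authors' table and in the fit of the 2 waters alone. Without exposure 2, 15 passed and without exposure 3, 14; gstp1.2 passed in both (adjusted p = 0.000116 and 6.4e-05) and missed the threshold with median scaling (0.0528). All 6 genes that rose, and ugt1a1, prdx1 and si:ch211-93g23.2, missed it both without exposure 2 and without exposure 3. Against Control, gstp1.2 stood at 0.13 (SE 0.07), tcnbb at -0.10 (SE 0.23) and sqor at 0.17 (SE 0.09) in AOP-2, with limma adjusted p = 1 each. The RO arrays serve in this comparison and in RO against Control, so genes chosen as high in RO tend to fall against RO. The immune-responsive gene irg1l was not among the calls.

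From AOP-2 to FINAL, and from TAP to FINAL, no probe passed (0 by limma in each, 342 and 697 at an unadjusted p under 0.05, and 0 with the exposure block). The smallest p between AOP-2 and FINAL belonged to fggy (log2 -0.27), hacl1 (-0.39), the keratin krt99 (0.35, higher in 12 of 12 pairs), invs (-0.38) and dis3l (-0.30). Between TAP and FINAL it belonged to xkr7a (1.05), dap1b (0.84), prcc (-0.33), ica1 (-0.80) and lgals2a (0.27). All had a limma adjusted p of 1. Without exposure 3 the counts were 27 and 26, where each water has 1 array per hour and the spread is taken from the other groups. The cyp1a difference between FINAL and TAP was -1.32 (SE 0.42, adjusted p = 1), lower in 12 of 12 pairs.

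At single hours 150 differences from Control passed over the 7 waters, and 795 with the exposure block. With water names exchanged within exposure and hour, 90 of 100 arrangements gave as many (median of the others 538). The count is therefore within what exchanged names give, and the genes named at single hours are not told apart from chance by it. In RAW, 41 probes rose and 0 fell at 12 h, among them cyp1b1 (log2 5.27), mixl1 (3.61) and ripor3 (above background on 1 of 3 RAW and 0 of 3 Control arrays, SD 3.52 in RAW, so the call rests on a single RAW array). At 8 h, 8 passed in RAW, including falls of slc32a1, scdb and tmem178a, which were above background on 0 of 3 RAW arrays and on 2, 1 and 1 of 3 Control arrays. The Control levels of slc32a1 (0.81, -2.73 and -5.86) and tmem178a (-2.13, -5.20 and -6.69) were highest in exposure 1. In MF and AOP-1 at 12 h cyp1b1 passed (5.15 and 4.96), with cav4b in MF (at least 2.80-fold higher, with 0 of 3 Control arrays above background). The 12 h Control arrays that RAW, MF and AOP-1 share had cyp1b1 at -3.57, -5.02 and -7.44. As 1 of 3 lay above background, the sizes of these differences are uncertain. The ATP synthase subunit atp5mc3b passed in MF, AOP-1 and RO at 12 h and ugdh in RO, but both rest on the Control array of exposure 2 that these comparisons share. That array had atp5mc3b at -0.29, against 4.84 and 5.13 on the other Control arrays, and ugdh at -7.12, against 1.49 and 1.42. In AOP-1 at 16 h, 14 passed: fabp4b, gjb1a and kcnj1a.2 were above background on at most 2 of 3 AOP-1 arrays and 0 of 3 Control arrays, and e2f4, dclk1a and cyb5b, lower in AOP-1, had an SD of 4.79, 2.58 and 2.57 there.

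In RO, crygs1 passed at 12 h (at least 3.39-fold higher), irg1l (log2 3.39) and tcnbb (at least 2.27-fold higher) at 16 h, and the receptor gene npffr1l3 at 24 h (at least 3.06-fold lower). At 48 h ch25hl1.1 (1.3, limma adjusted p = 0.000285), ugt5a4 (at least 2.52-fold higher), trim35-30 (above background on 1 of 3 RO arrays) and ca15c (-2.89) passed. In TAP, csf1a passed at 8 h (at least 1.24-fold lower, but at a log2 of -0.14 with adjusted p = 1 under normexp), and ch25hl1.1 (1.39), anxa1b (1.05) and rhcga (at least 3.19-fold lower) at 48 h. The bounds stand where 0 arrays of a group were above background.

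In AOP-2 and FINAL at 8 h the transcription factor nfe2 and the respiratory subunit uqcrc1 passed, but both rest in large part on the shared Control array of exposure 3, with nfe2 at -4.82 (-2.73 and -2.77 on the others) and uqcrc1 at 0.22 (1.42 and 1.18). At the same hour pdk2b passed in AOP-2 (0 of 2 Control arrays above background, at least 3.44-fold higher) and mfng in FINAL (above background on 1 of 2 FINAL and 0 of 2 Control arrays, SD 1.66 in FINAL, so it rests on a single array). At 12 h tmem178a passed in both and plppr5a in FINAL (at least 2.25-fold lower), each above background on 0 of 2 arrays of the water and 1 of 2 Control arrays. At 24 h plscr3a passed in FINAL (at least 10.21-fold higher, with 0 of 2 Control arrays above background), and at 48 h anxa1b (1.62) and anxa1c (-1.13) in AOP-2 and ch25h in FINAL (at least 5.64-fold higher, SD 2.82 there). Further calls rest on a single array. Control of exposure 2 at 12 h had naa15a at -7.12 (3.48 and 3.71 on the others) and polr1b at -2.61 (1.74 and 1.59). Control of exposure 3 at 48 h had mapre3a at 6.66 (-5.25 and -4.70 on the others) and ftsj1 at 2.92 (-0.70 and -0.93), and these passed as lower in RO and FINAL. In FINAL, atp1b2a and snx33 had an SD of 7.14 and 6.51 over 2 arrays at 12 h, and zgc:171776 and rtca, higher at 48 h, of 2.43 and 2.21. The genes si:ch211-10a23.2 at 8 h and mb at 12 h passed in FINAL with no array of either water above background.

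Counts at single hours moved with the exposure block. At 8 h it gave 302 in RAW, 12 in MF, 16 in AOP-1, 9 in RO, 51 in TAP, 12 in AOP-2 and 11 in FINAL. At 12 h it gave 162 in RAW, 17 in MF, 17 in AOP-1, 19 in RO, 5 in AOP-2 and 35 in FINAL, at 16 h 25 in AOP-1, and at 48 h 11 in MF, 28 in RO, 7 in TAP and 11 in AOP-2. Without the RAW 12 h array of exposure 1 the 150 became 145, and without the RAW 24 h array of exposure 1 136. Without exposure 1, 2 or 3 it was 285, 609 or 926.

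A change that differed between hours was found for 5 probes over the 7 waters (26 with the exposure block), 3 in RAW and 2 in RO. Over the 252 tests of a list in a water, 37 passed at the preset correlation and 7 with an estimated one: the AhR-responsive list in RAW, MF and AOP-1, the hypoxia and the maternal and germ line list in RAW, and the oxidative stress and the epidermis list in RO. The exposure block gave 42 and 7. With water names exchanged within exposure and hour, the median was 25 lists at the preset correlation, and 15 of 100 arrangements reached 37. The preset p of a list is therefore not a measure against chance here. Calls with an estimated correlation were not put through the exchanges.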

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

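The tests of the exchange with the RAW 36 h array and of the dim array, and the count of calls with a low Control value, below were chosen after the results were seen. A moderated F test asked, for each comparison of waters, whether a gene's difference was equal at the 6 hours, and the genes with a symbol that passed it stand here. Against Control 5 probes passed, and 65 of 100 exchanges of the water names gave as many, so chance is not excluded for that count. In RAW against Control the gene was gapdhs, a glyceraldehyde phosphate dehydrogenase (limma adjusted p = 0.0124), with log2 differences of 2.72 at 12 h and 1.15 at 16 h and between -0.36 and -0.02 at the other hours. In RO against Control, ch25hl1.1 (0.0029) was 1.3 higher at 48 h and anxa1c (0.0207) 1.41 lower, at -1.41. In MF against RAW, the homeobox gene nkx3.3 (0.00614) was above background on 0 of 3 MF arrays and 2 of 3 RAW arrays at 16 h (at least 5.07-fold lower).

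In RO against AOP-1 there were 5 such genes. The potassium channel gene kcnj1a.2 (limma adjusted p = 2.03e-05) was at least 2.08-fold lower at 16 h, with 0 of 3 RO arrays above background, and at 2.69 at 48 h. The annexins anxa1b (1.24e-06) and anxa1c (0.00598) were at 1.87 and -1.55 at 48 h, ch25hl1.1 (0.00128) was at 1.19 at 48 h, and the connexin gene gjb1a (0.00598) was at least 3.52-fold lower at 16 h, with 0 of 3 RO arrays above background. With the exposure block each of these 9 results passed as well, with adjusted p from 4.29e-09 to 0.00816.

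The 41 probes higher in RAW at 12 h were weighed against technical causes. Without exposure 1, whose RAW array has the lowest share of spots well above background, their log2 differences had a median ratio of 0.895 to those from 3 exposures (quartiles 0.738 and 1.16; 41 of 41 kept their sign), which argues against that array as the cause. For 4 of the 41 (atp5mc3b, ugdh, naa15a and cxxc1b) the Control array of exposure 2 lay more than 1 (log2) below both other Control arrays, so those calls rest on it, and for 37 it did not. A difference in stage stays open: a share of 0.756 (SE 0.0671) of the 41 moved in the direction of the 8 to 16 h course of TAP, MF, AOP-1 and RO, which does not decide it. An effect of the water remains untested apart from stage. Over all waters, 90 of 100 arrangements of exchanged names gave as many calls at single hours, so chance is not excluded either.

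The RAW 24 h array of exposure 1, which resembled 33.75 h, was weighed next. An exchange with the RAW 36 h array of the same exposure would leave that array at 24 h, and it resembled 36 h. The array is not dim: 87.8% of its spots were well above background, against a median of 73.2% (62.1 to 78.5) on the 21 other arrays of 24 h. RNA of Control embryos is argued against by cyp1a, 1.63 above the highest Control array of 24 and 36 h (3.05 on the array, 0.37 to 1.42 in Control and 3.40 to 3.49 on the other RAW 24 h arrays). A pool collected late or a mixed pool was not tested.

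The 20 probes called in RO against Control were weighed for slide, stage and dim arrays. With slide as a block the median ratio of their log2 differences was 0.942 (quartiles 0.918 and 0.974), and 14 of 20 passed. The change expected from the stage shift made up 0.0773 of that observed (quartiles 0.0148 and 0.0968), and without the 3 RO and 3 Control arrays lowest in spots above background the ratio was 1.08 (1.03 to 1.15), with 19 of 20 past. The differences thus kept most of their size under the slide block and without the dim arrays, and the stage shift made up little of them. These checks used probes called in the same data, and most arrays remained when the dim ones were left out. They do not cover the dependence of the calls on the exposures, and chance is not excluded. An effect of the RO water therefore stays a hypothesis that these checks do not decide.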

How the results depend on the processing

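The fits without the RAW 12 h array, without the RAW 24 h array, and with the exposure block and 1 exposure left out were chosen after the data were seen; the others were planned. Among 1565 alternative values for genes named in comparisons of waters, 1343 kept direction and side of the threshold, 203 fell short of it, 16 passed it and 3 reversed. Of 1002 values for genes at single hours 747 kept both, 254 fell short and 1 reversed. Of 848 for genes of the time course 847 kept both and 1 fell short. Of 439 for lists 296 kept both, 142 fell short and 1 reversed, and of 82 for the stage index 77 kept both, 3 passed and 2 reversed. Of 323 alternative counts 221 stayed within 1.5 times. Except where a setting's construction shows it (fewer arrays or probes), the cause was not tested.

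Counts that moved are given by setting, with counts at an unadjusted p under 0.05 for limma counts of 0. In the authors' log2 table the counts were AOP-1 11, TAP 1, AOP-2 5 and FINAL 4 against Control, AOP-1 against MF 2, FINAL against AOP-2 2, FINAL against TAP 2, MF against RAW 6, RO against AOP-1 31, single hours 970, interaction 122 and stage index 1; si:ch211-10a23.2 in FINAL at 8 h reversed to 0.30. Normexp gave FINAL 1, stage index 1, interaction 19 and single hours 235, and csf1a in TAP reversed to 0.043. Quantile scaling gave AOP-2 1, FINAL 1, interaction 23 and single hours 544. Median scaling gave AOP-2 0 (361), FINAL 0 (534) and AOP-2 against RO 8. Higher and lower calls split 8 and 3 in AOP-1, 5 and 2 in MF, 4 and 1 in AOP-2 and 3 and 1 in FINAL in the authors' table, 14 and 0 in RO with median scaling, and 1 and 1 in MF against RAW with quantile scaling.

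The exposure block gave RAW 27, MF 8, RO 40, MF against RAW 6, RO against AOP-1 44, interaction 26 and single hours 795. With exposure as an additive block, MF against RAW was 5 and interaction 8. A label date block gave MF against RAW 6. Slide as a fixed block gave AOP-2 1, FINAL 0 (1977) and single hours 246, and slide as a random block AOP-2 against RO 68, RO against AOP-1 37, interaction 18 and single hours 371. The stricter filter gave AOP-1 1, MF 1, RAW 5, RO 13, RO against AOP-1 9 and single hours 77. Fits of the 2 waters alone gave RAW 2, RO 2, AOP-1 0 (270), AOP-2 0 (258), FINAL 0 (739), MF against RAW 0 (869), AOP-2 against RO 13 and RO against AOP-1 10. Moderation without a trend, and Control of all 3 exposures, each gave AOP-2 1 and FINAL 1. Camera with an estimated correlation passed 7 lists in the waters and 15 in the time course, and fry 3 in the waters.

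Leaving out 1 exposure gave RAW 0 to 11, MF 0 to 4, AOP-1 0 to 3, RO 0 to 42, AOP-2 5 to 12 and FINAL 3 to 38 against Control, MF against RAW 0 to 6, RO against AOP-1 1 to 38, AOP-2 against RO 14 to 15, FINAL against AOP-2 1 to 27, FINAL against TAP 0 to 26, single hours 285 to 926, interaction 7 to 148 (141 without exposure 3) and stage index 0 to 1. With the block and 1 exposure left out it gave RAW 8 to 40, MF 3 to 7, AOP-1 3 to 4, RO 2 to 54, MF against RAW 0 to 9 and RO against AOP-1 7 to 46. The limma counts of 0 at an unadjusted p under 0.05 were 817 for RAW, 356 for MF, 333 for AOP-1, 486 for RO, 637 for MF against RAW (1918 with the block) and 365 for FINAL against TAP. Where 1 array is left in a group its spread is assumed to be that of the others. Over the exposures left out, 4 results reversed: the gastrula list in RAW (camera p 2.79e-09 to 0.641, reversed without exposure 3), the stage index in RAW (-0.312 to 1.79) and TAP (-0.062 to 0.646), each reversed without exposure 1, and trpv6 in RAW (-0.579 to 0.274), reversed without exposure 2.

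Signal over background limits what can be read: 36821 of 43603 probes were kept, and levels near background bound a fold from one side. Normexp was planned on the mean spot intensity and was run on the median.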

Other observations

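The tests of shared Control values and of lower oxygen below were chosen after the results were seen. Both genes in this paragraph were picked after their values were seen, and the calls at single hours are within what exchanged names give. At 48 h the carbonic anhydrase ca15c was lower in RO (log2 -2.89, limma adjusted p = 0.00108, above background on 1 of 3 arrays) and the ammonium transporter rhcga was at least 3.19-fold lower in TAP (adjusted p = 0.0242, above background on 0 of 3).

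At 48 h ch25hl1.1 and anxa1b lay above Control in TAP (1.39 and 1.05), RO (1.3 and 1.21), AOP-2 (1.49 and 1.62) and FINAL (1.48 and 1.49), and not in RAW (-0.05 and -0.94), MF (-0.07 and -0.85) or AOP-1 (0.11 and -0.66). Low values in the shared Control arrays would raise all 7 waters. The mean of RAW, MF and AOP-1 over that of the other 4 was -0.296 (means -0.41 and 1.38), where that explanation needs at least 0.5. The SD of 0.429 is over 2 genes picked for this pattern and measures no sampling error. The waters were grouped by these same values, so the ratio was bound to be low and decides nothing.

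In RAW, egln3, mixl1 and maternal genes stood above Control. A candidate explanation is that some embryos in the RAW pools were held at an earlier stage. The 200 probes that fall most from 8 to 12 h in other waters had a median of 0.717 above Control in RAW at 12 h, and -0.395 to -0.247 in the other waters, but the exposures differed (0.435, -0.40 and 2.22), so it stays open and rests mainly on exposure 3. Other values go the opposite way. Of the 41 probes higher in RAW at 12 h, a share of 0.756 rose along the 8 to 16 h course, which is towards a later stage. The 12 h arrays of RAW resembled 12.25, 11.75 and 11 h in exposures 1, 2 and 3, against 11.75, 11.25 and 12.75 h in Control. Lower oxygen in the RAW dishes may be another: without egln3, ldha and p4ha1b the hypoxia list had a camera p of 0.000614 with an estimated correlation (15 genes, 10 above 0, median 0.14), and 0.0133 without aldocb and pfkfb3 as well (13 genes, 8 above 0). Lower oxygen needs such values, but the test reuses the list that raised the idea, MF had 0.0213 with 12 of 15 above 0 and AOP-1 and RO 11 and 10, and oxygen is not among the values used here, so it stays open. The list members aldocb and ldha also rise from 8 to 16 h in the other waters (log2 2.31 and 1.40), while egln3 does not (-0.25). Oxygen and stage are therefore not separated for those 2 genes.

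Exchanging the names of the compared waters within exposure and hour, in 100 arrangements with the real one, showed which counts exchanged names can give. Missing cells were filled with group means there, so some real counts differ by a few from those above. Counting the real one, under 0.05 of the arrangements gave as many calls for RAW (1 of 100 as large, 10 calls, highest other 2), MF (1, 5 and 0), AOP-1 (1, 4 and 0), RO (1, 20 and 1), RO against AOP-1 (1, 20 and 8) and AOP-2 against RO (1, 26 and 17). The same held for AOP-2 (2, 2 and 2), FINAL (3, 2 and 2) and MF against RAW (2, 3 and 3), where other arrangements reached the real count. Names were exchanged pair by pair, so hours of the same exposure counted as independent. With 3 or 2 independent exposures, these shares do not exclude chance. In the comparisons with 0 limma calls every arrangement gave as many: TAP (100, 0 and 1, with 391 at an unadjusted p under 0.05), AOP-1 against MF (100, 0 and 0, 381), FINAL against AOP-2 (100, 0 and 0, 342) and FINAL against TAP (100, 0 and 0, 697).

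Chance is also not excluded for the 150 calls at single hours (90 of 100 as large, highest other 17424), the 5 of the interaction (65, 507) or the 37 lists in waters (15, 54). An arrangement with 17424 calls points to a structure of the samples, which was not identified. With the RAW 24 h array of exposure 1 drawn as Control (13 exchanges) the median was 870 calls, against 501 in the other 86, of which 76 also reached 150. The arrangement with 17424 calls was among the 86, where the array had another water's name, and with it as Control the highest was 4089, so its use as Control did not give the 17424; its part as an array of another water was not tested. For the time course lists the hours of the Control arrays were exchanged within each exposure, and 77 of 100 gave as many (56 real, 78 highest). Arrays with exchanged hours still come from different stages, so this is no measure of what chance gives and decides nothing about these lists. For the steps of the time course the 10 splits of 3 against 3 arrays, of which 1, the real one, gave as many, are too few for a share under 0.05: 10442 real and 3842 highest other for 8 to 12 h, 5038 and 51 for 12 to 16 h, 8191 and 22 for 16 to 24 h, 3021 and 1 for 24 to 36 h, 1556 and 5 for 36 to 48 h, and 24340 and 10982 for 8 to 48 h.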
